A study of Homo sapiens with 4 samples.

How the data were processed

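The data were 1 table of expression values for 33297 probe sets on 4 whole-transcript GeneChip arrays. Per the labels' protocols, stable MCF-7 transfectants were kept under puromycin, total RNA was extracted with TRIsure, and the target was labelled with biotin using a GeneChip whole-transcript terminal labelling kit. The values deposited by the authors are on a log2 scale, as judged from their range, and the summarisation, background correction and normalization that made them are not given in the sources used here. The 4 arrays had close but not identical medians over all probe sets (6.50, 6.49, 6.58 and 6.52), so they were on a common scale without being quantile-identical. How the mammospheres were grown, and whether the arrays came from separate cultures, is not given in the sources used here.

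Groups were taken from the labels of cell type and construct, which gave MCF-7 control, MCF-7 DYRK2 shRNA, mammosphere control and mammosphere DYRK2 shRNA with 1 array each. Probe sets were named from the platform annotation: 19460 had 1 gene symbol, 1754 had several and were not used, and 12083 had none listed. Symbols were updated through gene numbers in the RefSeq table of GRCh38.p14, which matched 19429 probe sets. For 769 of the 18417 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was kept. A gene was compared when its highest value over the 4 arrays reached 6.97, the median of all gene-named values, which left 10343 genes. AR, TP53, UBR5, NANOG and POU5F1, though on the list of study genes, were on no probe set with a single gene name and are not analysed here. Signal near the dim end can compress differences, but values there are also less certain. A large difference for a gene that is dim on some arrays may therefore be too small or too large. PRG4, above the limit in MCF-7 control only, had an averaged culture effect of -2.36 with an SE of 1.45.

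Each of the 4 differences (DYRK2 shRNA minus control in each culture, and mammosphere minus MCF-7 with each construct) was a subtraction of log2 values with no test, and genes at least 1 log2 unit apart were counted. The spread of a single difference over genes of like brightness was taken within 0.5 log2 units. The construct and culture effects averaged over the other factor were tested with limma 3.58.1 in R 4.3.3 (lmFit with both factors as additive terms, eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05 over 10343 genes. With 1 residual degree of freedom, the construct-by-culture difference serves as the error, so the test asks whether a difference is the same in both cultures beyond their disagreement. The prior had 3.07 degrees of freedom. Overlaps were set beside the number that independent lists of the same sizes would share. The differences compared had no array in common, but a gene that varies between any arrays can enter both lists, so independence is not assured.

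Of 37 gene lists fixed for the cell type and treatment, 35 had at least 3 members above the brightness limit. The list of mitochondrially encoded genes had 0 measured members and the leukocyte and endothelial list had 2 above the limit. For each list the median difference was placed among 10000 random lists of the same size drawn from 10 brightness bins, a description of these arrays and not a test across replicates, and intervals of medians came from 10000 bootstrap resamples of the members. The number of members passing limma was counted over all genes and adjusted over the list alone.

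Named genes followed a rule. For single differences and for the construct-by-culture difference these were the 5 genes per direction with the largest size, and for averaged effects the 10 per direction with the largest smaller-of-2 difference among genes at least 1 unit apart the same way in both, because fewer than 10 passed limma. All study genes and DYRK2-related kinases above the limit could be named, and up to 4 members of every other list with the largest averaged effect. Non-coding and placeholder symbols were given as classes. List members that passed when adjusted over the list alone, genes named to illustrate the reversal between cultures and the genes SNORD116-14 and SNORD116-15 were chosen after their values were seen.

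The limma step was tested on simulated data for the construct effect with 200 changed genes among 10343: 0 of 67 genes were called at a log2 size of 1, 1 of 67 (1.49%) at 2 and 52 of 66 (78.8%) at 4, beside 2 of 10143 unchanged genes. The simulated effects were equal in both cultures and the noise had an assumed size. No construct-by-culture difference was included, so these rates need not hold for these arrays. In a check of the list step with 25 members per list, 19 of 20 lists shifted by 0.5 were found and 2 of 20 lists with no shift fell outside the central 95%. Groups, tests, lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring on array medians, no brightness limit, a limit at the 75th percentile, the mean of a gene's probe sets, an offset of 32 added on the linear scale, a 1.5-fold threshold, limma without the trend and unmoderated residuals. Other tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.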

Results

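Transcript levels were measured in MCF-7, an established luminal, estrogen receptor-positive breast cancer cell line, after stable silencing of DYRK2, a dual-specificity tyrosine-regulated kinase. The stated interest of the study was whether DYRK2 governs the stem-like population of breast cancer cells. Short hairpin RNA against DYRK2 (DYRK2 shRNA) was delivered in the pSuper vector, and cells with the vector alone served as control. RNA was taken from MCF-7 cells and from mammospheres, floating spheres that are commonly grown to enrich for stem-like breast cells. This gave 4 groups with 1 whole-transcript GeneChip array each: MCF-7 control, MCF-7 DYRK2 shRNA, mammosphere control and mammosphere DYRK2 shRNA. The arrays held 33297 probe sets, of which 19460 named a single gene, and 10343 genes were bright enough to be compared. The median log2 value per array over all probe sets was 6.50, 6.49, 6.58 and 6.52 in that order. Pearson correlations across probe sets between pairs of arrays ran from 0.968, between the DYRK2 shRNA arrays of the 2 cultures, to 0.982, between the 2 MCF-7 arrays. With 1 array per group, no difference between a pair of arrays has a replicate check or a p-value, and the number of arrays limits the precision of every value. All levels and differences are on the log2 scale, on which 1 unit is 2-fold.

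DYRK2 itself was lower in the DYRK2 shRNA array of both cultures. Its level was 8.53 in MCF-7 control and 7.53 in MCF-7 DYRK2 shRNA, a difference of -1.0 that left 49.9% of the control level. In mammospheres it was 8.54 in control and 8.02 with DYRK2 shRNA, a difference of -0.52 that left 70.0%. Among 3299 genes of like brightness, 2.67% were at least as low as DYRK2 in the MCF-7 difference and 9.06% in the mammosphere difference, so the lower level stood out less from other genes in mammospheres. DYRK2 was at nearly equal levels in the 2 control arrays, with a mammosphere minus MCF-7 difference of 0.00. Averaged over both cultures the DYRK2 difference was -0.76 (SE 0.24 from limma), and it did not pass limma's test after adjustment.

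Of the study genes, KLF4 and CD44 differed with DYRK2 shRNA by at least 1 unit in opposite directions in the 2 cultures. KLF4, a pluripotency transcription factor, was higher by 1.33 in MCF-7 (8.54 in control, 9.87 with DYRK2 shRNA) and differed by -1.20 in mammospheres (9.95 and 8.75). CD44, the hyaluronan receptor used as a breast cancer stem cell marker, was higher by 2.23 in MCF-7 (9.28 and 11.51) and differed by -3.12 in mammospheres (11.69 and 8.57). JUN, an AP-1 subunit, showed 0.72 in MCF-7 and -1.55 in mammospheres, while the MYC transcription factor showed -0.25 and 1.48. SOX2, another pluripotency factor, was lower in both, by -0.43 and -2.37. In the control arrays, mammospheres had more KLF4 than MCF-7 cells by 1.41, more CD44 by 2.41, more JUN by 2.28 and more SOX2 by 1.10. Averaged over both cultures, KLF4 differed by 0.06 (SE 0.68) and CD44 by -0.44 (SE 1.35), so neither differed by more than its disagreement between cultures.

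Other genes of that list stayed closer together. CD24, a surface protein that is low on stem-like breast cells, differed by -0.10 in MCF-7 and 0.43 in mammospheres, and the cell cycle inhibitor CDKN1A by 0.59 and -0.11. SNAI1, a repressor of E-cadherin, showed -0.71 in mammospheres and -0.03 in MCF-7, where centring the arrays on their medians turned the sign. The acetyltransferase KAT5 differed by 0.06 and 0.31, the ubiquitin ligase parts DDB1 by -0.34 and 0.42 and DCAF1 by -0.11 and 0.25, and the ubiquitin ligase SIAH2 by 0.16 and 0.06. ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, was under the brightness limit on all 4 arrays. Kinases related to DYRK2 were mostly within 1 unit with DYRK2 shRNA: DYRK1A differed by 0.06 in MCF-7 and -0.32 in mammospheres, and CLK1 by 0.52 and -0.25. The exception was HIPK2, a kinase that phosphorylates p53, at -0.06 in MCF-7 and 1.29 in mammospheres. The medians of the 13 study genes and of the 10 kinases of the family above the brightness limit lay within the central 95% of 10000 random gene lists of like brightness in all 4 differences.

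**Figure D1:**
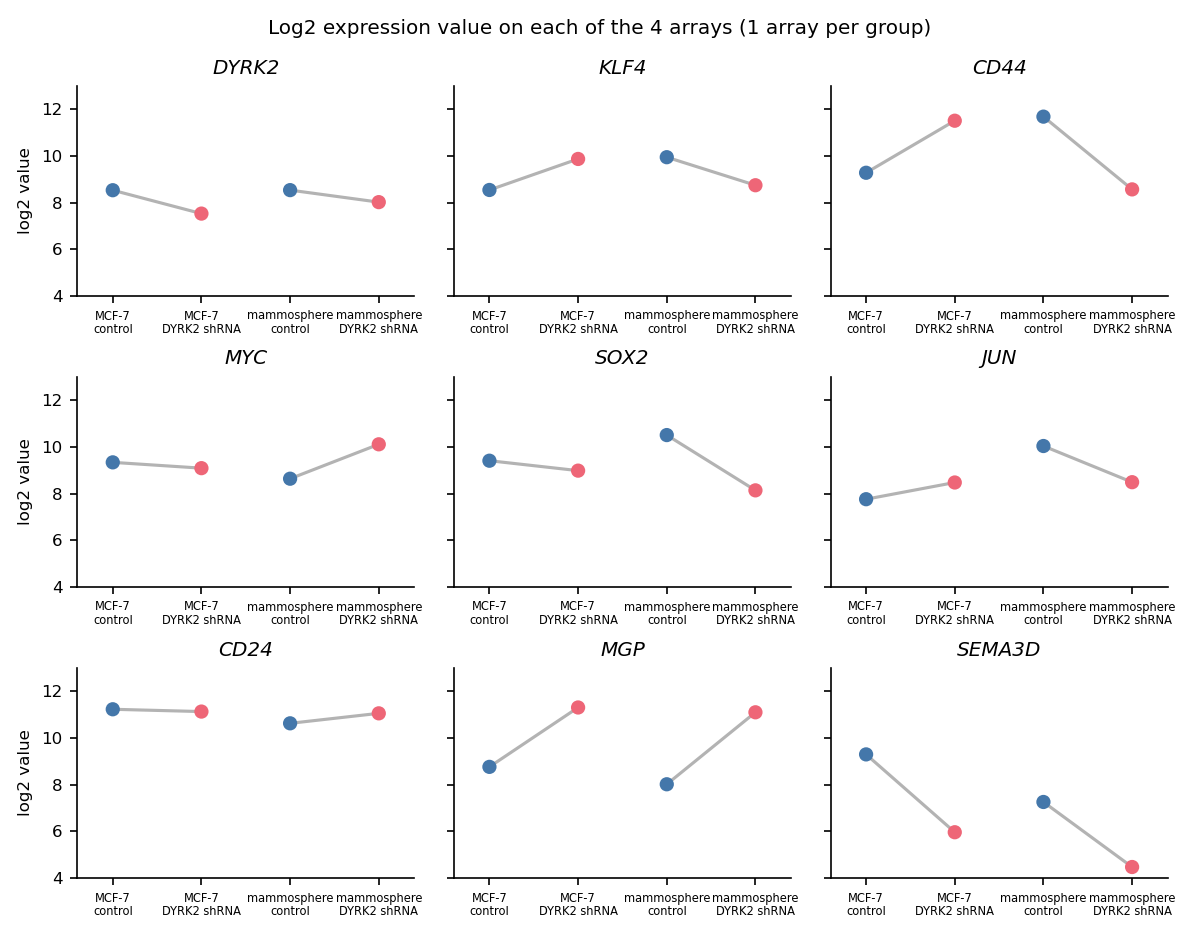
Log2 level (vertical axis) of 9 genes on each of the 4 arrays (horizontal axis), 1 point per array with no error bar because each group had 1 array. CD44 lay at 9.28 in MCF-7 control, 11.51 in MCF-7 DYRK2 shRNA, 11.69 in mammosphere control and 8.57 in mammosphere DYRK2 shRNA, and KLF4 was likewise highest in mammosphere control, at 9.95.

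In MCF-7 cells, the gene furthest above control with DYRK2 shRNA was CEACAM5, the carcinoembryonic antigen, which was higher by 3.96. It was followed by S100A7, the calcium-binding protein psoriasin (3.65), the chitinase-like CHI3L2 (3.13), the adhesion protein CEACAM6 (3.02) and the calpain protease CAPN9 (2.95). Lower genes were led by MMP16, a membrane-bound metalloproteinase, at 8.67 in control and 4.10 with DYRK2 shRNA, a difference of -4.57. The protocadherin PCDH10 differed by -3.73, the secreted guidance protein SEMA3D by -3.34, the polysialyltransferase ST8SIA4 by -3.16 and NR3C1, the glucocorticoid receptor, by -3.07. In all, 267 genes were higher and 287 lower by at least 1 unit.

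Genes of amino acid supply and estrogen response were higher as groups in MCF-7 with DYRK2 shRNA. Of 25 ATF4 target genes, which serve amino acid synthesis and import under stress, 8 were higher and 1 lower by at least 1 unit, with a median of 0.91. They included the cystine exchanger subunit SLC7A11 (2.05), asparagine synthetase ASNS (1.84) and stanniocalcin STC2 (1.61), which is on the estrogen receptor list as well. The 24 estrogen receptor targets had a median of 0.59 with 6 higher and 3 lower, among them MYBL1 at 1.5 and PGR, the progesterone receptor, at 1.39, against CXCL12, a chemokine, at -2.67. The 23 MYC targets, many of which build ribosomes and process RNA, had a median of -0.72, and all 23 were below control, 6 of them by at least 1 unit. NOLC1 differed by -1.59, DKC1 by -1.12 and ODC1, the first enzyme of polyamine synthesis, by -0.87. Mitotic genes were slightly lower, with a median of -0.41 over 30 genes (CDC20 -0.97, PLK1 -0.80), and 17 TGF-beta and BMP pathway genes had a median of -0.38 (BAMBI -2.01, TGFB1 -1.68). These 5 medians lay outside the central 95% of the random lists, and 12 of the 35 lists did so in this difference. For TGF-beta and BMP genes the bootstrap interval over genes spanned 0 (-1.05 to 0.11). The mitosis list was not lower with DYRK2 shRNA in mammospheres, where 22 genes were higher and 8 lower. Its median there was 0.23, within the random range.

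In mammospheres, the DYRK2 shRNA array stood apart from control by its interferon-response genes. IFIT1, an interferon-induced protein that binds foreign RNA, was at 6.07 in control and 11.75 with DYRK2 shRNA, a difference of 5.67. IFI44L was higher by 5.07, the helicase DDX60 by 4.36, IFIT2 by 4.04 and the oligoadenylate synthetase OAS2 by 3.54. Of 37 measured interferon-response genes, 32 passed the brightness limit on their highest array. IFIT1, IFI44L and DDX60 reached it only in the mammosphere DYRK2 shRNA array, so the limit favoured genes that were high there. Of these 32 genes, all were higher and 28 were higher by at least 1 unit, with a median of 2.32 against 0.25 in MCF-7, where 4 were. The lysozyme gene LYZ and CD68, the members of the leukocyte marker list above the brightness limit, did not share this direction and differed by -4.65 and -0.96.

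Outside the interferon genes, SLC26A2, a sulfate transporter, was higher by 5.66 and the adaptor FYB2 by 4.49. Lower genes were ADGRF1, an adhesion receptor (-5.34), OLFM4, a secreted glycoprotein (-5.19), SLC6A14, an amino acid transporter (-5.13), GUCY1A1, a guanylate cyclase subunit (-5.05), and the receptor tyrosine kinase ERBB4 (-4.98). In all, 408 genes were higher and 381 lower by at least 1 unit. The hypoxia and glycolysis list, 30 genes, had a median of 0.43 with 6 higher and 1 lower (CA12 2.79, BNIP3 1.59, HK2 1.28, against EGLN3 -1.43). Nuclear-encoded oxidative phosphorylation genes, 31 in all, also had a median of 0.43, with COX7B at 1.35. ATF4 targets had a median of 0.47 (STC2 1.22, SLC7A5 1.21), 15 androgen receptor targets one of 0.39 (PIP, a secreted breast protein, 3.51, and STEAP4, a metalloreductase, -2.42), and MYC targets one of 0.36. The p53 targets, 21 genes, had a median of -0.30, with CCNG1 at -0.73, and 22 AP-1 and immediate early genes one of -0.31, with DUSP6, a phosphatase that restrains ERK, at -1.95. Each of these list medians lay outside the central 95% of random lists, and 13 of the 35 lists did so in this difference. The bootstrap interval over genes spanned 0 for ATF4 targets (-0.04 to 0.60), androgen receptor targets (-0.54 to 1.45) and AP-1 and immediate early genes (-0.62 to 0.15).

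A small set of genes differed by at least 1 unit the same way with DYRK2 shRNA in both cultures. MGP, the matrix Gla protein that restrains calcification, was higher by 2.55 in MCF-7 and 3.09 in mammospheres, an average of 2.82 (SE 0.29). SAMD9, an antiviral factor, was higher by 2.34 and 2.05, S100A7 by 3.65 and 1.58, S100A7A by 2.59 and 1.64, and AZGP1, a secreted zinc-binding glycoprotein, by 1.74 and 1.5. The interferon-induced genes IFI6 (1.72 and 2.92), OAS1 (1.37 and 2.25) and IFI27 (1.80 and 1.30) were also higher in both, as were the transcription factor MYBL1 (1.5 and 1.55) and SLC7A11 (2.05 and 1.28). Among the lower genes, SEMA3D differed by -3.34 and -2.79, the ubiquitin ligase MID1 by -2.34 and -3.93, the ephrin receptors EPHA4 by -1.69 and -1.72 and EPHA7 by -1.37 and -2.38, the slit receptor ROBO1 by -1.39 and -3.20, and SLITRK6 by -1.47 and -3.61. TMTC1 (-1.51 and -2.83), the calcium-binding NECAB1 (-1.42 and -3.32), PLEKHS1 (-1.39 and -2.0) and ANKRD34B (-1.32 and -1.63) completed the 10 lowest. The WNT antagonist DKK1 was lower in both as well, by -1.07 and -1.50.

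In total 19 genes were higher and 22 lower in both cultures, where independent lists of these sizes would share 10.5 and 10.6. Opposite directions exceeded independent lists by more (82 genes against 9.84 and 76 against 11.3), so this excess is not evidence of a shared response. No gene passed limma's test of the averaged construct effect: 0 were called at an adjusted threshold of 0.05, and 207 had an unadjusted p under 0.05, where 517 would be found by chance. The smallest p belonged to MGP, with a limma adjusted p of 1. Without limma's intensity trend there were 0 calls and 191 genes under the unadjusted threshold, and with unmoderated residuals 0 calls and 380. Adjusted over the list alone and not across lists, 4 interferon-response genes (IFI6, IFI27, OAS1 and SAMD9) and 1 androgen receptor target (AZGP1) passed, against 0 over all genes. The spread in this test was the disagreement between the cultures, with 1 residual degree of freedom. In simulated data the test called 0 of 67 genes with a true size of 1 and 1 of 67 with a size of 2. At a size of 4 it called 52 of 66. Those data held no construct-by-culture difference, so the rates need not hold here. On these arrays EHF, with an averaged culture effect of 4.79, was not called.

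Far more genes differed with DYRK2 shRNA in opposite directions in the 2 cultures than in the same direction. CD44, CEACAM5, the matrix protein TGFBI and the stress-induced cytokine GDF15 were higher in MCF-7 and lower in mammospheres, whereas MMP16, SLC26A2, the apoptosis inhibitor BCL2 and the carbonic anhydrase CA12 went the other way. By at least 1 unit in each culture, 82 genes were higher in MCF-7 and lower in mammospheres, where independent lists would share 9.84. Another 76 were lower in MCF-7 and higher in mammospheres, where 11.3 would be shared. The 2 differences had no array in common, and their correlation across genes, which are not independent replicates, was -0.24. Of the 74 genes at least 2 units apart in MCF-7, 43 (58.1%) had the opposite sign in mammospheres.

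The construct-by-culture difference, the mammosphere difference minus the MCF-7 difference, put sizes on this pattern. MMP16 stood highest at 8.32, followed by SLC26A2 (7.29), the actin-binding SYNPO2 (5.72), the growth hormone receptor GHR (5.67) and IFI44L (5.66). SLC6A14 stood lowest at -6.98, followed by CEACAM5 (-6.24), TMEM45A (-5.72), and ADGRF1 and TGFBI (-5.49 each). It reached at least 1 unit upward for 1031 genes and downward for 740. It made up 31.3% of the variance over the 4 arrays, beside 49.5% for culture and 19.2% for construct. These shares rest on the array labels as given, and exchanged labels are weighed further below. With MCF-7 DYRK2 shRNA and mammosphere control exchanged, culture would make up 19.2% and construct 49.5%. With the mammosphere labels exchanged, construct would make up 31.3% and the construct-by-culture difference 19.2%. Several genes with opposite directions were at like levels in MCF-7 DYRK2 shRNA and mammosphere control. Among them were CD44 at 11.51 and 11.69, KLF4 at 9.87 and 9.95 and TGFBI at 9.13 and 9.12. MYC targets shared the reversal as a group, with medians of -0.72 in MCF-7 and 0.36 in mammospheres. The p53 targets had medians in the other direction, 0.26 and -0.30, but the interval over genes in MCF-7 spanned 0 (-0.06 to 0.35). Their median construct-by-culture difference was -0.52, with 17 of 21 genes below 0. Mitosis genes had medians of -0.41 and 0.23, the second within the random range. Their median construct-by-culture difference was 0.71, with 26 of 30 genes above 0. With no residual degree of freedom for this difference, its values were not tested.

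**Figure D2:**
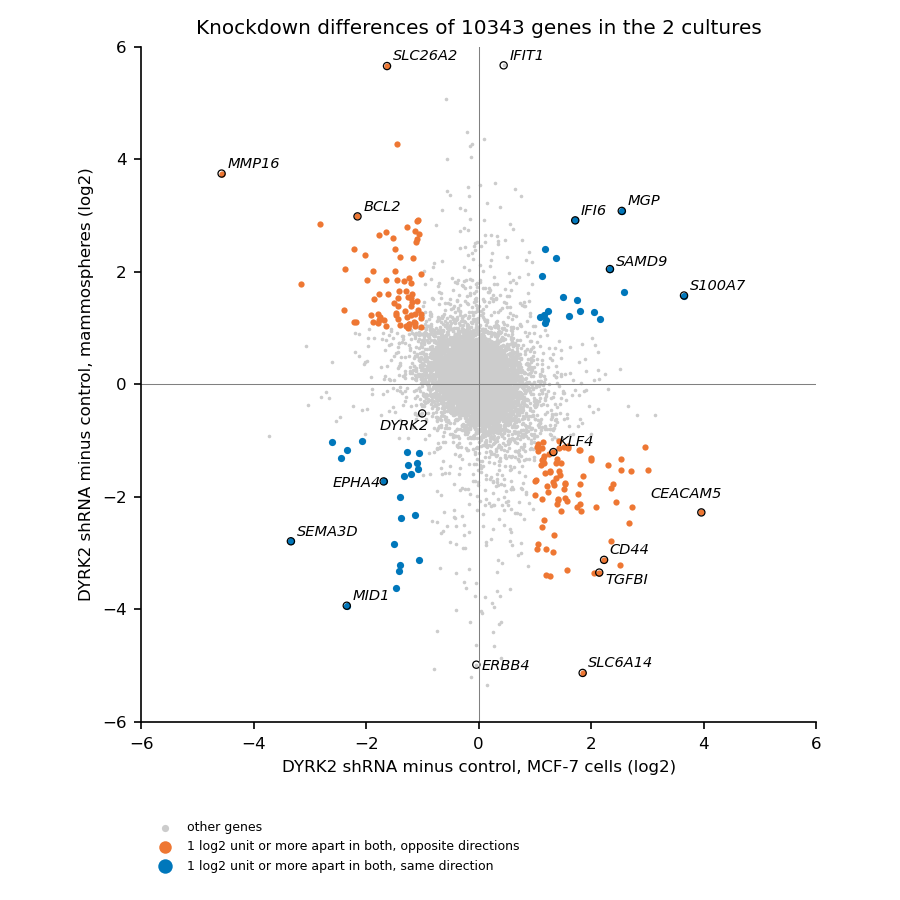
DYRK2 shRNA minus control difference (log2) in MCF-7 cells (horizontal axis) against mammospheres (vertical axis), 1 point per gene for 10343 genes. The 158 genes at least 1 unit apart in opposite directions are orange, the 41 apart in the same direction are blue, and the correlation across genes was -0.24.

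With the control construct, the gene furthest above MCF-7 cells in mammospheres was BPIFB1, a secreted defence protein of mucosal surfaces, at 6.32. It was followed by GUCY1A1 (5.95), the membrane protein TM4SF1 (5.82), BPIFA1, a relative of BPIFB1 (5.66), and CP, the copper carrier ceruloplasmin (5.65). MMP16 differed by -3.78, FREM2, an extracellular matrix protein, by -3.67, the collagen COL12A1 by -3.52, the GTPase RAB30 by -3.43 and the hormone stanniocalcin STC1 by -3.35. The count of genes at least 1 unit apart was 534 higher and 573 lower. The p53 target list had a median of 0.60 with 6 of 21 genes higher by at least 1 unit (TP53INP1 1.59, SPATA18 1.40, the death receptor FAS 1.27). Higher medians were also found for androgen receptor targets (0.59) and for AP-1 and immediate early genes (0.37, DUSP6 2.84). Pluripotency and stem cell transcription factors had a median of 0.61 over 9 genes, among them KLF5 at 1.92 and SOX2 at 1.10. MYC targets had a median of -0.76, with LDHA, a glycolytic enzyme, at -1.28. All these medians lay outside the central 95% of random lists. The interval over genes spanned 0 for the pluripotency and stem cell factors (-0.15 to 1.41) and the androgen receptor targets (-0.08 to 1.42).

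Among DYRK2 shRNA arrays, the mammosphere minus MCF-7 difference was led by PIP, the prolactin-induced protein of breast secretions, at 6.43, IFIT1 at 6.40, SLC26A2 at 6.08, IFI44L at 5.81 and DDX60 at 5.72. The lowest genes were SLC6A14 at -5.97, the fatty acid elongase ELOVL2 at -4.77, PGR at -4.70, the adhesion protein AMIGO2 at -4.69 and the calcitonin receptor CALCR at -4.66. The interferon list had a median of 2.61 with 27 of 32 genes higher by at least 1 unit, against 0.76 and 13 genes in the control arrays. Pluripotency and stem cell transcription factors had a median of 0.06, within the random range and -0.36 with a stricter brightness limit, and KLF5 and SOX2 stood at -0.76 and -0.85. MYC targets had a median of 0.37 here, opposite to the control arrays, and the ATF4 list one of -0.77 (STC2 -1.92, SLC7A5 -1.30). At least 1 unit separated 590 genes upward and 592 downward.

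With the array labels as given, genes of the cell cycle were lower in mammospheres than in MCF-7 cells with either construct. All 30 genes of mitosis were lower in both, with medians of -1.83 in control and -1.21 with DYRK2 shRNA, and all 30 genes of the G1/S transition and DNA replication were lower in both, with medians of -1.30 and -1.30. RRM2, a subunit of ribonucleotide reductase, differed by -2.63 and -1.99, the checkpoint mediator CLSPN by -2.29 and -2.06, the spindle factor TPX2 by -2.42 and -1.44, the mitotic kinase PLK1 by -2.13 and -1.36 and ANLN, a cytokinesis scaffold, by -1.83 and -2.20. Replication-dependent histone genes, which are transcribed in S phase, had medians of -0.78 and -0.68 over 38 genes, with H1-5 at -2.08 and -1.74. Estrogen receptor targets were also lower, with medians of -0.80 and -1.03 over 24 genes, led by PGR (-2.65 and -4.70), GREB1 (-3.32 and -2.25) and MYBL1 (-2.15 and -2.10). The kinetochore gene SPC25 (-2.55 and -2.16) and the protease FAM111B (-2.41 and -2.35), were among the 10 lowest shared genes, as were CAV1, the coat protein of caveolae (-3.30 and -4.46), and ELOVL2 (-3.10 and -4.77). PGR and GREB1 were also among those 10, and the remaining 4 were RBM24 (-2.39 and -2.73), SYTL5 (-2.30 and -2.26), PRG4 (-2.50 and -2.22) and SLC4A10 (-2.19 and -4.14).

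Higher in mammospheres with either construct was EHF, an epithelial transcription factor, by 5.03 in control and 4.55 with DYRK2 shRNA, an average of 4.79 (SE 0.24). TM4SF1 was higher by 5.82 and 4.19, CYP4Z1, a mammary cytochrome, by 4.23 and 5.48, its pseudogene CYP4Z2P by 2.79 and 3.82, CDC20B by 5.33 and 3.23 and BPIFB1 by 6.32 and 2.92. AZGP1 (3.24 and 2.99), PDK4, a kinase that blocks pyruvate oxidation (2.89 and 2.87), FAR2, a fatty acyl reductase (2.78 and 3.70), and OAS1 (2.74 and 3.63) completed the 10 highest. CYP4Z1 and CYP4Z2P have near-identical sequences, so their probe sets cannot be read as separate measurements. In all, 133 genes were higher and 215 lower by at least 1 unit with both constructs, where independent lists would share 30.5 and 32.8. Opposite directions were also more frequent than in independent lists, with 66 genes higher in control and lower with DYRK2 shRNA against 30.6, and 51 the other way against 32.7. The correlation of the 2 differences across genes was 0.23.

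No gene passed limma's test of the averaged culture effect over all genes. There were 0 calls at an adjusted threshold of 0.05, and 893 genes had an unadjusted p under 0.05, where 517 would be found by chance. EHF had the smallest p, with a limma adjusted p of 0.290. Without the intensity trend there were 0 calls and 889 genes under the unadjusted threshold, and with unmoderated residuals 0 calls and 612. Adjusted over the list alone, 30 of 30 mitosis genes, 28 of 30 G1/S genes, 6 of 32 interferon genes, 5 of 24 estrogen receptor targets (GREB1, PGR, STC2, CTSD and MYBL1), 4 of 38 histone genes (H1-5, H2BC9, H2BC14 and H3C2) and 3 of 15 androgen receptor targets (ELL2, AZGP1 and PIP) passed. CAV1 and ACTA2 of the basal list passed as well, in opposite directions (averages of -3.88 and 1.63). So did PDK4, FKBP4, LTBP1 and B2M, 1 from each of 4 other lists. Together these came to 82 members over all lists, with B2M counted for both the interferon list and the control genes. The adjustment did not extend across lists, and members of a list were read from the same 4 arrays, so they are not separate observations.

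**Figure D3:**
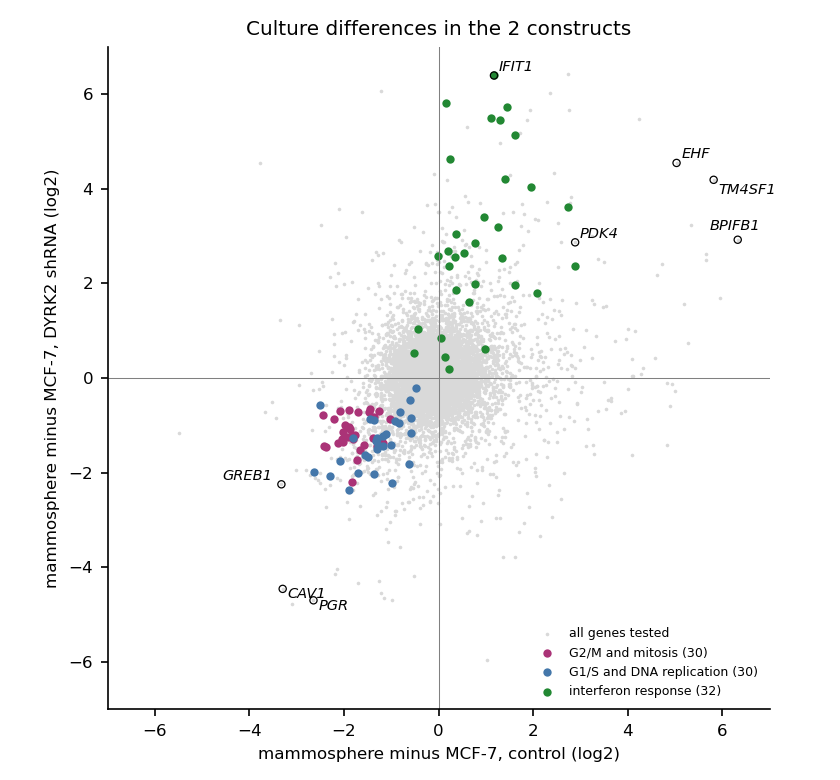
Mammosphere minus MCF-7 difference (log2) in the control construct (horizontal axis) against DYRK2 shRNA (vertical axis), 1 point per gene for 10343 genes, with 3 gene lists coloured. All 30 mitosis genes and all 30 G1/S genes lay below 0 on both axes, and the 32 interferon genes had medians of 0.76 and 2.61.

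The luminal epithelial list, 23 genes, had medians between -0.16 and 0.17 in the 4 differences (mean -0.07 where the median was 0.17), all within the central 95% of random lists. With DYRK2 shRNA averaged over both cultures its median was 0.16, above that range. Single members moved apart, such as TFF3, a trefoil peptide, at 0.09 in MCF-7 and -2.30 in mammospheres with DYRK2 shRNA. Mesenchymal and EMT genes, 15 in all, had medians between -0.12 and 0.03 and means between -0.26 and -0.01, with TGFBI at 2.15 and -3.34 and THBS1, thrombospondin, at -1.64 and -0.12 with DYRK2 shRNA. Their median of 0.03 in mammosphere against MCF-7 control became -0.64 with a stricter brightness limit. Breast cancer stem cell markers, 12 genes, had medians of -0.09 in MCF-7 and 0.01 in mammospheres with DYRK2 shRNA. Their signs turned with other settings, the first to 0.33 with a stricter brightness limit. In mammospheres against MCF-7 cells the median was -0.29 in control and 0.00 with DYRK2 shRNA, within the random range, and -0.36 averaged over both, outside it. The interval over genes of that average spanned 0 (-0.71 to 0.34). The members diverged with DYRK2 shRNA, and the efflux pump ABCG2 differed by -2.20 in MCF-7 and 0.91 in mammospheres. Basal and myoepithelial genes, 9 in all, differed from these lists in having medians outside the random range in single differences. Their median with DYRK2 shRNA was -0.41 in mammospheres, outside the random range, and 0.08 in MCF-7, where their mean was -0.22, with the peptidase MME at -2.60 and -1.03 in MCF-7 and mammospheres and EGFR, the epidermal growth factor receptor, at 0.45 and -2.0. Mammospheres lay below MCF-7 cells in this list by a median of -0.51 in control, outside the random range, and of -0.32 with DYRK2 shRNA, within it.

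Unfolded protein response, YAP/TAZ target, and Notch and Hedgehog lists were within the random range in all 4 differences, but 11 of 13 Notch and Hedgehog genes were lower when DYRK2 shRNA was averaged over both cultures, with a median of -0.25 outside that range. Of the 35 lists, 16 lay outside it for the averaged construct effect and 21 for the averaged culture effect. The NRF2 and metallothionein list, 17 genes, had medians of 0.38 in MCF-7 and 0.30 in mammospheres with DYRK2 shRNA, outside the random range in both, with the metal-binding MT2A at 0.66 and 1.21. In mammospheres its interval over genes spanned 0 (-0.61 to 1.01). Cholesterol biosynthesis genes, 19 in all, had a median of -0.34 in MCF-7 and 0.03 in mammospheres, and 14 heat shock genes -0.35 and 0.03, with the co-chaperone BAG3 at -1.02 and 1.97. Fatty acid and lipid droplet genes, 17 in all, had a median of 0.43 in mammospheres with DYRK2 shRNA and of -0.17 in MCF-7, where the value was 0.10 without the brightness limit. Of 12 control genes, the median was -0.06 in MCF-7 and 0.29 in mammospheres with DYRK2 shRNA, and -0.55 in mammosphere against MCF-7 control, which lay below the random range. In that last difference TUBB, a tubulin, was at -1.53 and B2M, the light chain of HLA class I, at 1.62. Fibroblast markers were mostly too dim to compare, and the 3 above the limit (COL1A1, COL6A1 and COL6A2) had medians within the random range in all 4 differences, the lowest single value being -0.49 for COL1A1 in mammospheres with DYRK2 shRNA.

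**Figure D4:**
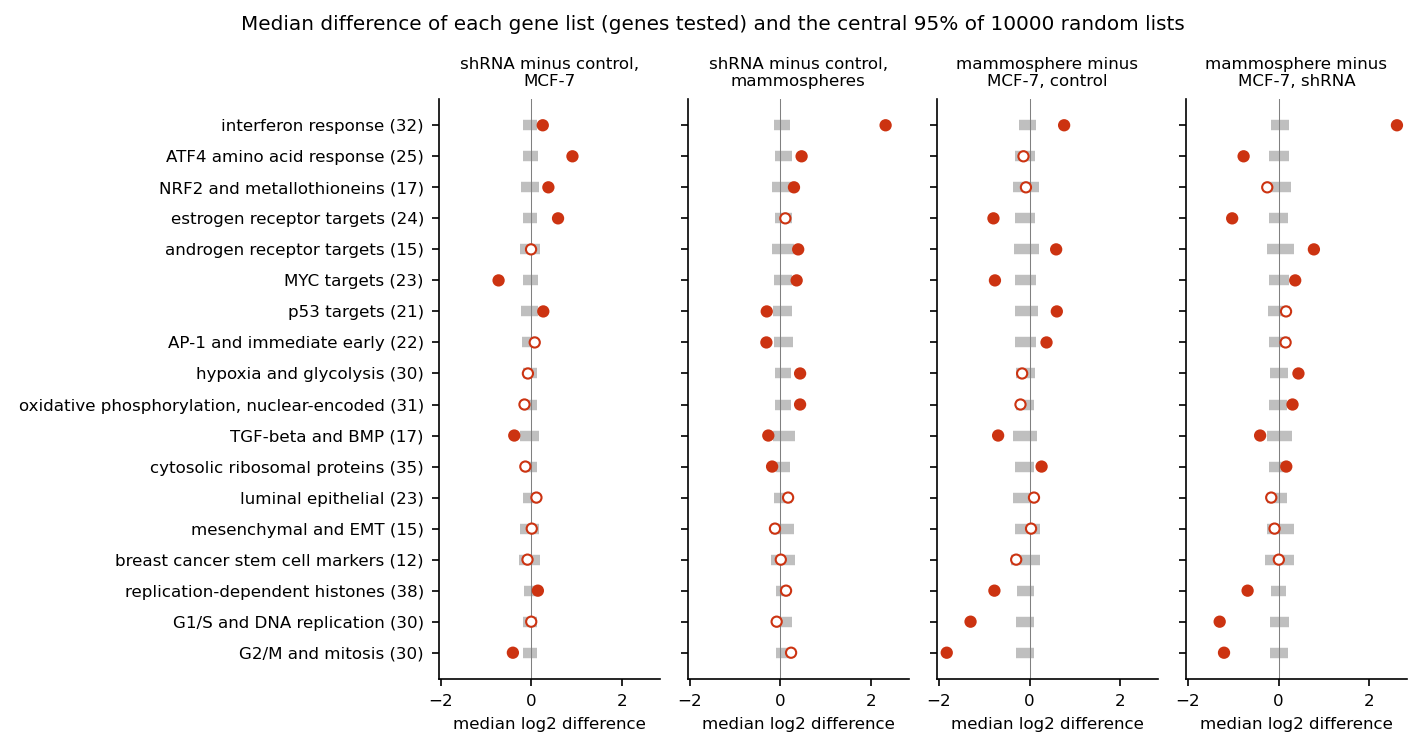
Median log2 difference (horizontal axis) of 18 gene lists in each of the 4 differences, with a grey bar for the central 95% of 10000 random lists of the same size and brightness, and a filled point for a median outside it. The interferon list reached 2.32 in the mammosphere DYRK2 shRNA minus control difference, and the mitosis list -1.83 in the mammosphere minus MCF-7 difference of the control construct.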

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

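The exchanges of array labels were tested only after the opposite directions had been seen, while the test of a brightness trend was chosen beforehand. The results singled out here are, among the named genes, those whose DYRK2 shRNA difference had opposite signs by at least 1 log2 unit in MCF-7 cells and mammospheres, given as the mammosphere difference minus the MCF-7 difference, which with 1 array per group was not tested.

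For genes higher in MCF-7 and lower in mammospheres, the value was -6.98 for the amino acid transporter SLC6A14, -6.24 for CEACAM5, -5.72 for TMEM45A, -5.49 for the matrix protein TGFBI, -5.35 for CD44, -4.55 for CEACAM6, -4.07 for the protease CAPN9, -3.71 for the adhesion protein AMIGO2 and -3.15 for CP, ceruloplasmin. The stress cytokine GDF15 stood at -3.32, the epithelial transcription factor ELF3 at -2.67 and KLF4 at -2.53.

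Genes lower in MCF-7 and higher in mammospheres were led by the metalloproteinase MMP16 at 8.32, the sulfate transporter SLC26A2 at 7.29, the actin-binding SYNPO2 at 5.72 and the growth hormone receptor GHR at 5.67. The apoptosis inhibitor BCL2 stood at 5.14, the polysialyltransferase ST8SIA4 at 4.95, the carbonic anhydrase CA12 at 4.07, the collagen COL12A1 at 3.0, the co-chaperone BAG3 at 2.99, the chemokine receptor CXCR4 at 2.96, the matrix protein FREM2 at 2.94, the GTPase RAB30 at 2.58 and the transcription factor SNAI2 at 2.32. Lists also reversed: MYC targets had a median DYRK2 shRNA difference of -0.72 in MCF-7 and 0.36 in mammospheres, and a mammosphere minus MCF-7 difference of -0.76 in control and 0.37 with DYRK2 shRNA. The median of p53 targets was 0.26 in MCF-7, where the interval over genes spanned 0 (-0.06 to 0.35), and -0.30 in mammospheres. None of these differences was tested.

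For the reversal as a whole, 158 genes and a correlation of -0.24 across genes, a trend with brightness left by the normalization is argued against, since the running median over brightness lay only between -0.11 and 0.12 in either culture and the correlation was -0.247 after it was removed. Exchanged array labels stay open, judged by the averaged DYRK2 difference each would give in place of -0.76. With the 2 mammosphere labels exchanged it was -0.244 (SD 0.435 over 3299 genes of like brightness). With MCF-7 DYRK2 shRNA and mammosphere control exchanged it was 0.248 (SD 0.550). A value above 0 by more than 1 SD would have spoken against an exchange, and one below 0 by more than 1 SD for it. Neither exchange reached either bound. Each SD is a spread over genes and not the error of the DYRK2 value, so these wide bounds could hardly exclude an exchange. As labelled, DYRK2 was lower with shRNA in both cultures. The first exchange would turn the sign of its mammosphere difference of -0.52. The second would leave it lower in neither culture, with differences of 0.00 in MCF-7 and 0.49 in mammospheres. With single arrays, DYRK2 does not decide between them. The first exchange could produce the whole reversal. The second exchange would leave each construct-by-culture value given here as it is, but the genes apart in both cultures would become 117 opposite, 133 higher and 215 lower, with a correlation of 0.23. For the excess of opposite over same-direction genes it therefore cannot be told apart. Opposite genes would still exceed independent lists (66 against 30.6 and 51 against 32.7). It would also turn every mammosphere minus MCF-7 result, such as the lower cell cycle genes, into a DYRK2 shRNA minus control result, and the reverse. A culture-dependent response to DYRK2 loss, the biological alternative, and a difference between single cultures were not tested. Because the control was the vector alone, a response to the hairpin itself cannot be told apart from DYRK2 loss in either culture.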

How the results depend on the processing

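No gene passed limma for either averaged effect under any alternative that was fixed beforehand, and the correlations across genes kept their signs. Genes with an unadjusted p under 0.05 numbered 119 for construct and 565 for culture with a brightness limit at the 75th percentile, 396 and 1320 with no limit, and, over the same genes as in the main test, 380 and 612 with unmoderated residuals. The balance of genes higher and lower turned where the counts were close: with DYRK2 shRNA in MCF-7 it went from 267 and 287 to 288 and 249 with quantile normalization, 288 and 259 with median centring, 208 and 183 with the stricter limit and 206 and 186 with the offset, and for mammosphere against MCF-7 control from 534 and 573 to 658 and 622 with no limit. The near-equal counts for mammosphere against MCF-7 with DYRK2 shRNA (590 and 592) turned with no limit (729 and 667), probe set means (586 and 584) and the 1.5-fold threshold, and those shared by both cultures (19 and 22) with the stricter limit (16 and 15), the offset and the 1.5-fold threshold. Over the alternatives of normalization, brightness limit, probe sets and offset, 125 counts of genes apart, limma calls and correlations stayed within 1.5 times the main value and 7 moved. At the 1.5-fold threshold all 16 counts of genes apart moved. With the stricter limit, 183 genes were lower with DYRK2 shRNA in MCF-7 and 667 had a construct-by-culture difference of at least 1, fewer because fewer genes were compared. With an offset of 32, which shrinks differences of dim genes, 186 genes were lower in MCF-7, 12 lower in both cultures, 103 opposite in the cultures, 85 higher with both constructs and 76 opposite between constructs. At 1.5-fold, the counts higher and lower were 774 and 976 in MCF-7, 1234 and 850 in mammospheres, 1127 and 1623 for culture in control, 1399 and 1281 with DYRK2 shRNA, and 2313 and 1495 for the construct-by-culture difference. At that threshold 97 genes were higher and 77 lower in both cultures with 552 opposite, and 345 were higher and 480 lower with both constructs with 399 opposite. Quantile normalization kept 267 of the 267 genes higher and 249 of the 287 lower in MCF-7. It and median centring turned the sign of 21 values of named genes and list medians, the largest of them 0.07 in size, while filters and probe set averaging turned 29, the largest 0.25 before and, for mesenchymal genes in mammosphere against MCF-7 control, from 0.03 to -0.64. Over the alternatives of normalization, brightness limit, probe sets and offset, 2299 values of named genes kept their sign and stayed within 1.5 times the main value. Another 35 moved, and among list medians 664 stayed and 172 moved by the same bound. A brightness limit does not enter a gene's own value. The 389 values of named genes with no limit and the 389 with the stricter limit therefore could not move. Averaging probe sets could move only genes with more than 1, and 3 values moved there. Quantile normalization moved 13, median centring 8 and the offset 11. Leaving out 1 array of an averaged effect leaves a single difference with 0 residual degrees of freedom (for DYRK2, -1.0 or -0.52), so no test could be run. By the bound of 1.5 times, 628 such values of named genes moved from the average over all 4 arrays and 520 did not. Each single difference was counted once for each array of the other pair. Differences of genes near the dim end can be compressed or uncertain, and the array number limits the rest.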

Other observations

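The tests of a response to the hairpin and of array scaling were chosen only after the patterns had been seen, and those of leukocytes and of a second cell line before their results. Small nucleolar and Cajal body RNAs, which guide chemical modification of other RNAs, were higher in mammospheres than in MCF-7 cells with either construct. Over 99 members above the brightness limit the median difference was 0.82 in control, with 38 higher and 1 lower by at least 1 log2 unit, and 0.74 with DYRK2 shRNA, with 28 higher and 1 lower. DYRK2 shRNA itself went with medians of -0.11 in MCF-7 and -0.14 in mammospheres. SNORD116-14 and SNORD116-15, copies from an imprinted cluster, were higher in mammospheres by 2.75 and 2.35 in control and by 5.68 and 6.03 with DYRK2 shRNA. The copies of that cluster are alike in sequence, so their probe sets are not separate measurements.

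Ribosomal protein genes, 35 in all, had medians of 0.27 in control and 0.17 with DYRK2 shRNA in mammospheres against MCF-7 cells, and oxidative phosphorylation genes -0.20 and 0.31. The NF-kB and cytokine list had medians of 0.55 and 0.39 there, with the chemokines CCL20 at 2.12 and 0.56 and CXCL8 at 1.60 and 0.55. TGF-beta and BMP genes had medians of -0.69 and -0.41, with BMP7 at -0.92 and -2.89 and TGFB2 at -2.68 and -1.09. Adhesion genes, 26 in all, had medians of -0.40 and -0.17. LYZ, the lysozyme gene, was at 9.45 in mammosphere control and between 4.62 and 4.90 on the other 3 arrays.

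Interferon-response genes were high in the mammosphere DYRK2 shRNA array, with a median of 2.32 over control for 32 genes. Leukocytes in that sample stay open: the 14 measured leukocyte and endothelial markers had a median difference of -0.0605 (95% bootstrap interval -0.522 to 0.0586), which met the bound set beforehand, but all except LYZ and CD68 were under the brightness limit on all 4 arrays and were never seen to respond. A response to the hairpin wherever it is expressed could raise these genes, but a response of like size in both cultures was not seen. In MCF-7 the list's median difference was 0.251 (interval over genes -0.0388 to 0.460), smaller but above the random range, which ended at 0.113. This contrast was seen before the test was chosen and rests on 1 array per group, so it does not decide the cause. A response to the hairpin stays open for at least part of the pattern, since IFI6, IFI27, OAS1 and SAMD9 were higher by at least 1 unit in MCF-7 as well. A response to DYRK2 loss that depends on culture, and a chance difference between single cultures, were not tested.

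A set of 22 genes lay under the brightness limit of 6.97 in both MCF-7 arrays and was at least 2 log2 units higher in mammospheres with both constructs, among them EHF, TM4SF1, CYP4Z1, BPIFB1, CP and PIP. A scaling of the arrays that lifts dim genes is argued against, because the other 7063 genes with MCF-7 levels in the same range had a median difference of 0.0814 (SD 0.464) in control and -0.05 with DYRK2 shRNA. Cells of another line mixed into the mammospheres might bring such genes, and MTAP, in a region that MCF-7 is known to lack, was at most 5.6e-05 higher in mammospheres. That value met the bound set beforehand, but MTAP lay between 4.78 and 4.83 on all 4 arrays, under the brightness limit of 6.97, so its probe set was never seen to respond and the mixture stays open. A response of MCF-7 cells to growth as spheres is the biological alternative, and it cannot be told apart from such a mixture by these arrays.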
